A study of Setaria italica with 6 samples.

How the data were processed

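RNA from foxtail millet (Setaria italica) spikelets, taken 3 days after flowering from greenhouse plants, was sequenced in 6 libraries: 3 of the wild type, the inbred line Yugu1, and 3 of the mutant Siysl1. Per the labels' protocols the plants grew under a 14 h photoperiod at 30 °C. Total RNA was extracted with a column kit and made into mRNA libraries. The labels describe the 3 libraries of a genotype as separate individuals. The title of each library gave its genotype. The genotype field of Siysl1 replicates 2 and 3 names other YSL genes than SiYSL1, but their titles, the series' design text and the column names of both tables call all 3 libraries the ysl1 mutant, and the titles were followed.

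The authors deposited 2 tables with the same 36886 genes and 1 column per library. One holds raw counts, whole numbers per gene that were not normalized. The other holds FPKM, which by the name the authors gave the deposited table are fragments per kilobase scaled to library size. The aligner, the counting tool and the genome build are not given in the sources used here. Of the genes, 34584 carry an annotation identifier ending in v2.2 and 2302 carry an identifier of the form NewGene, called new loci here. How the new loci were defined is not given in the sources used here, nor is whether counting used strand, so overlapping and antisense genes may share reads, as may near-identical copies. A count was 0 wherever the FPKM was 0 in every cell of the tables. The length implied by each gene's count and FPKM varied between libraries by a coefficient of variation of 0.168% (median over genes with at least 50 counts in all 6 libraries). No row of the count table lacked a gene.

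No source used here pairs these identifiers with gene names. The supplied RefSeq gene table (assembly Setaria_italica_v2.0) matched 0 of the 36886 identifiers. The planned tests of SiYSL1 itself, of the other YSL genes and of 20 gene lists chosen by gene description were therefore not run, including the lists meant as markers of other parts of the spikelet. The planned rule named the 10 largest rises and falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher genotype and no overlap between genotypes. Because identifiers without names say little, only the first 2 of each direction are named. The chromosome number and serial number inside each identifier were used as written to group genes and to order them along chromosomes. The 34264 identifiers with a chromosome number run in serial steps without a gap. No coordinates were used, so the planned windows of 2 Mb were replaced by windows of 50 tested genes in identifier order. The plan for windows set all called against tested genes. Windows were instead tested for changes of at least 4-fold only, a second departure from the plan, and not for all called genes.

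The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling, the default filterByExpr filter, genotype as the only term and Benjamini-Hochberg adjustment; genes with an adjusted p under 0.05 were called. It tested 25117 genes and left out 11769, of which 5003 had no count in any library. The standard error of a log2 fold change was taken as its size divided by the square root of F. On simulated counts for these 25117 genes with 200 changed genes, the test recovered 64% of 1.5-fold, 88% of 2-fold and 96% of 4-fold changes for this comparison, with 18 false calls. Of 50 genes changed at each of 1.5-, 2-, 4- and 8-fold, 32, 44, 48 and 48 were recovered. Beside these recovered genes, the 18 false calls were a larger share of all calls than the 0.05 aimed for, in 1 simulation. The simulation changed far fewer genes than the 14727 called in the data, so its recovery and false calls may not hold there. CPM values, counts scaled to library size, were computed with the TMM library sizes.

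Genes with counts in 1 genotype only were defined as those with 0 counts in all 3 libraries of one genotype and at least 10 counts in each library of the other. A count of 0 allows up to 3 counts in a library, and folds against silent libraries were set against that floor. Intervals for shares are exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only. Chromosomes were compared by Fisher's exact test, each against the other 8. Genes are not independent replicates, so tests across genes describe these libraries. Values per library were compared by exact two-sided permutation tests, which cannot go below 0.1 with 3 libraries against 3.

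Library totals lay between 30368325 and 32691355 counts. Replicate pairs differed by 2.14 to 7.52 chi-square units per gene, above the 1 that counting noise alone gives, so no library was taken as a repeat deposit, and the common biological coefficient of variation was 0.0638. Same-numbered libraries of the genotypes deviated together only weakly (r = 0.06, 0.07 and 0.04 across genes), under the limit of 0.1, so the numbers were not taken as pairs.

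Alternatives fixed before the data were examined were a replicate block, DESeq2 1.42.0 size factors, upper-quartile scaling, DESeq2 itself, other count filters, limma 3.58.1 with a mean-variance trend on log2 FPKM with a pseudocount of 1 or 0.1, fold thresholds, leaving out each library, and Siysl1 replicate 1 alone. The alternatives with no scaling factor, without the 100 most abundant genes, with a test against a 1.5-fold change, with chromosomes tested within expression quartiles at each of 3 fold thresholds (exact Mantel-Haenszel test, adjusted over the 9 chromosomes at each), and with other count minimums for genes of 1 genotype were added after seeing the data, as was the definition of those genes.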

Results

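The transcriptome of developing spikelets was compared between wild-type foxtail millet and the mutant Siysl1, 3 days after flowering. SiYSL1 belongs by its name to the yellow stripe-like family, whose members carry iron and other metals bound to nicotianamine or phytosiderophores across membranes. The study asks by its title whether the gene takes part in iron uptake, transport and accumulation in the grain, and the comparison asks which transcripts differ in the mutant. Each genotype had 3 libraries. Total counts were 31233000 ± 874850 (SD, n = 3) in WT and 31775000 ± 984240 in Siysl1, a difference within the spread between replicates (exact permutation p = 0.5). The transcript of SiYSL1 itself was not analysed here, because no source used here pairs its name with an identifier, so the mutation was not checked in the libraries.

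The 2 genotypes differed across most of the expressed genes. Of 25117 genes tested, 7515 were higher and 7212 lower in Siysl1 (edgeR quasi-likelihood test, adjusted p under 0.05), which is 58.6% of those tested. Most of these changes were small. The median absolute log2 fold change of the called genes was 0.62, and 10075 of them (68.4%) changed by less than 2-fold. At least 2-fold changes were found in 2741 genes that rose and 1911 that fell, so that 58.9% of them were higher in Siysl1 (52.2% with Siysl1 replicate 1 alone against WT); limma on log2(FPKM + 1), a scale that shrinks folds of weak genes, gave 1643 and 842. That fit also changed the tool, the input, the filter and the scaling. With a pseudocount of 0.1 limma gave 2309 higher and 1093 lower, so the scale alone is not shown to account for the drop. Among changes of at least 4-fold the directions were nearly even, with 754 genes higher and 749 lower. The genotypes did not overlap in any library for 64.0% of the tested genes, against the 10% that chance gives with 3 libraries against 3.

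**Figure D1:**
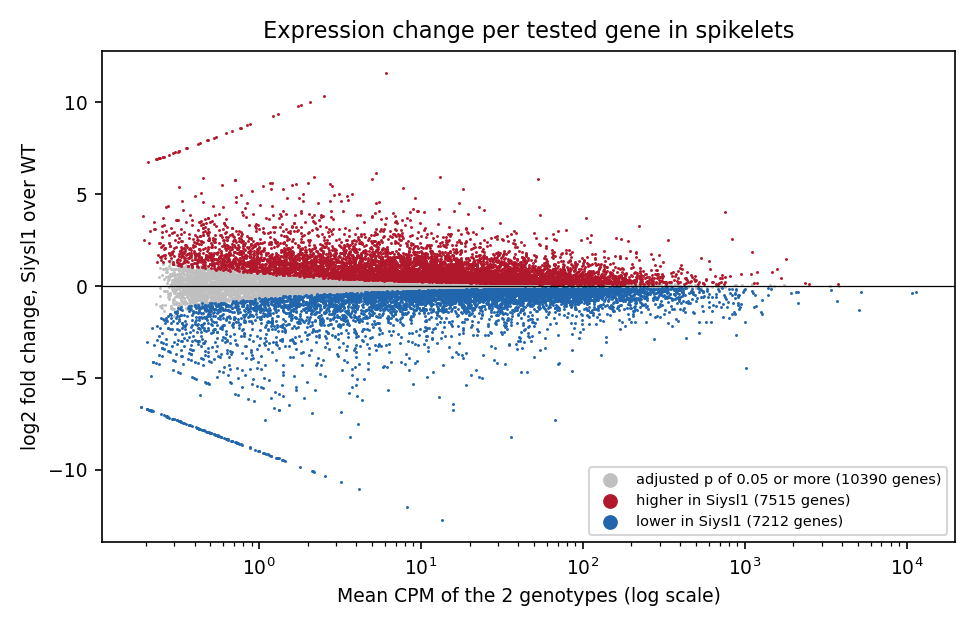
Each point is 1 of the 25117 tested genes, placed by its mean CPM (log axis) and its log2 fold change, with called genes coloured by direction. The 7515 higher and 7212 lower genes cover the whole range of expression, and the straight rows of points at the outer left are genes with 0 counts in 1 genotype, whose fitted fold depends on a prior count.

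Libraries of a genotype were close to each other. Correlations of log2 CPM across genes were 0.99 within genotypes and 0.92 to 0.93 between them, and the first principal component separated the genotypes and held 84.5% of the variance, against 4.72% for the next. On the second component Siysl1 replicate 1 lay at 34.6 and replicates 2 and 3, the 2 whose genotype field names another YSL gene, at -16.3 and -17.7, while the WT libraries ran from -12.0 to 8.97. Replicates 2 and 3 of Siysl1 correlated at 0.9927 with each other and at 0.9899 and 0.9895 with replicate 1, against 0.9896 to 0.9905 among the WT pairs. Without Siysl1 replicate 1, 15127 genes were called, 13951 of them also called with all libraries. With Siysl1 replicate 1 alone against WT, the only library for which every label names SiYSL1, 12248 genes were called, and 11289 of them were also called with all libraries. Without a scaling factor the called genes were 9266 higher and 5564 lower, so the share higher moved from 51.0% to 62.5%, with the median of all tested genes shifted to 0.11 on the log2 scale from 0.01.

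Some genes had counts in 1 genotype only. In WT alone 121 genes had at least 10 counts in every library and 0 counts in all Siysl1 libraries, and in Siysl1 alone 37 genes had counts. WT-only genes thus made up 76.6% of these genes (95% interval 69.2 to 82.9%). Set against a floor of 3 counts per library, the fold bound was at least 16 in 33 WT-only and 9 Siysl1-only genes, with medians of 11 and 8.45. Most of them are thus not shown to change by 16-fold. Another 206 genes with counts in both genotypes reached 16-fold, but by fitted fold and without any floor. The sizes of change in these genes and in the silent ones were therefore not compared. The genes named next came first by fitted fold under the naming rule, and that order depends on a prior count. Seita.3G022700.v2.2 on chromosome 3 had 27.1 ± 0.57 CPM in WT (SD, n = 3; 820, 805 and 822 counts) and none in Siysl1, at least 296-fold lower. Seita.2G367200.v2.2 on chromosome 2 had 16.3 ± 1.17 CPM in WT and none in Siysl1, at least 179-fold lower. In the other direction, the new locus NewGene_1602 had 12.2 ± 0.64 CPM in Siysl1 (414, 402 and 387 counts) and none in WT, at least 123-fold higher. Seita.2G107000.v2.2 on chromosome 2 had 5.06 ± 0.99 CPM in Siysl1 and none in WT, at least 50.8-fold higher. All 4 passed the edgeR test with adjusted p of 9.18e-14, 1.44e-12, 4.73e-12 and 1.45e-09 in the order given. Their folds are bounds against the same floor of 3 counts per library. The counts of such genes follow the minimum chosen: at 5 counts they were 202 in WT and 74 in Siysl1, and at 30 counts 44 and 14. Leaving out a library can only keep or add such genes, and without WT replicate 2 the Siysl1-only count was 60.

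Genes of 1 genotype were spread over the genome. The WT-only genes lay on all 9 chromosomes, with 5 to 19 on each, 4 on unplaced sequence and 6 among the new loci. The Siysl1-only genes lay on 8 chromosomes, none on chromosome 1, and 7 were new loci. New loci made up 18.9% of the Siysl1-only and 4.96% of the WT-only genes (Fisher's exact test, two-sided p = 0.0131). On chromosome 3 there was a run of 4 neighbouring WT-only genes, the longest, and 14 WT-only genes stood in 6 runs in all. The Siysl1-only genes had 1 run of 2, on chromosome 2.

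**Figure D2:**
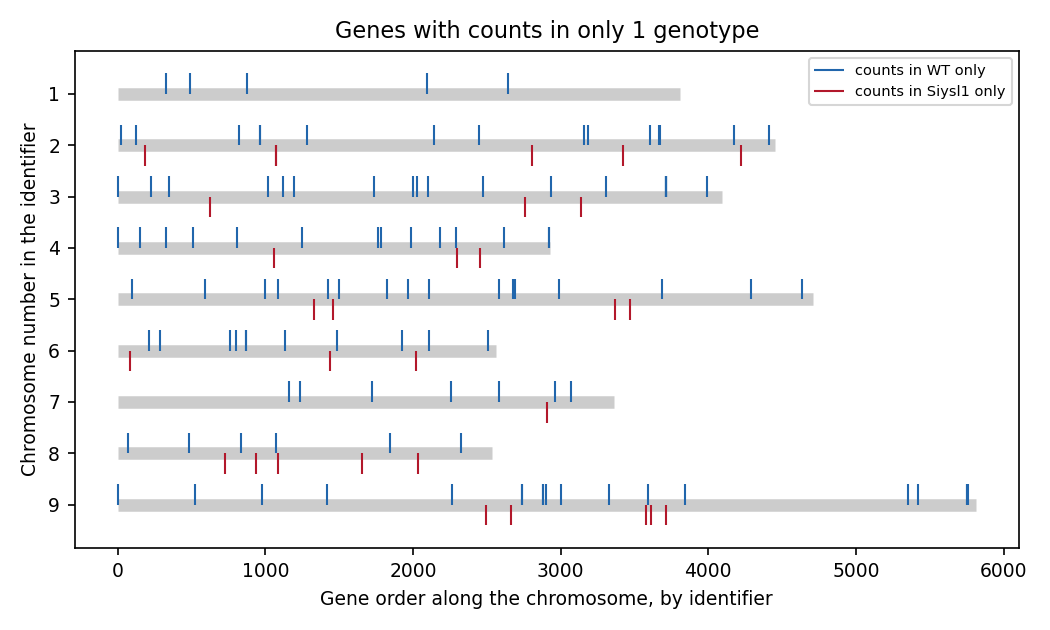
Grey bars are the 9 chromosomes, drawn by the number of annotated genes in identifier order, with a blue tick above for each WT-only gene and a red tick below for each Siysl1-only gene. The 111 WT-only ticks occur on every chromosome and outnumber the 30 Siysl1-only ticks on each.

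Highly expressed genes more often fell. Of the 100 most abundant genes 61 were lower, 25 higher and 14 not called, and of the 1000 most abundant 517 were lower and 250 higher. Without a scaling factor lower genes were still the more frequent, 53 against 33 and 391 against 340. Ranked by counts summed over all 6 libraries, the first 3 genes belong to a group of 4 within 9 neighbouring identifiers on chromosome 6; in WT alone the third of them, at 5823 CPM, lay below a gene on chromosome 8 at 7236 CPM. Each of the 3 was lower in Siysl1, with log2 fold changes of -0.33 ± 0.05 (SE), -0.39 ± 0.04 and -0.34 ± 0.06, and the fourth was higher by 0.13 ± 0.04, all with adjusted p under 0.05 in edgeR. Together the 4 genes held 34450 ± 1118 CPM in WT and 28060 ± 444 CPM in Siysl1 (SD, n = 3), 0.815 of the WT level, with no overlap of the libraries (exact permutation p = 0.1, the smallest possible). The largest change among the first 10 genes of this ranking was that of the chromosome 8 gene, which had 7236 ± 45.0 CPM in WT and 2900 ± 257 CPM in Siysl1 (log2 fold change -1.32 ± 0.05, edgeR adjusted p = 3.53e-12). A gene on chromosome 9 fell from 4744 ± 136 to 2676 ± 57.4 CPM (adjusted p = 1.45e-11). The 10 most abundant genes of each library, its own and not those of this ranking, took 5.80% ± 0.12 of the counts in WT and 4.82% ± 0.03 in Siysl1 (exact permutation p = 0.1, the smallest possible).

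Direction depended on expression level across the whole transcriptome. In the highest quartile of mean CPM, above 40.2 CPM, 1616 called genes were higher and 2653 lower, so 37.9% were higher. Over the other 3 quartiles 5899 were higher and 4559 lower, or 56.4% higher (Fisher's exact test across genes, odds ratio 0.471, p = 2.57e-93). The quartile between 2.81 and 12.7 CPM leaned most to higher values, with 2265 genes higher and 1387 lower. Without a scaling factor 54.1% of the called genes in the highest quartile were higher, so its excess of lower genes rests on scaling; it stayed the lowest share of the 4 quartiles under every scaling tried, TMM, DESeq2 size factors, upper-quartile and none. Large changes were concentrated in weakly expressed genes. At least 4-fold changes made up 14.9% of the lowest quartile and 1.32% of the highest.

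**Figure D3:**
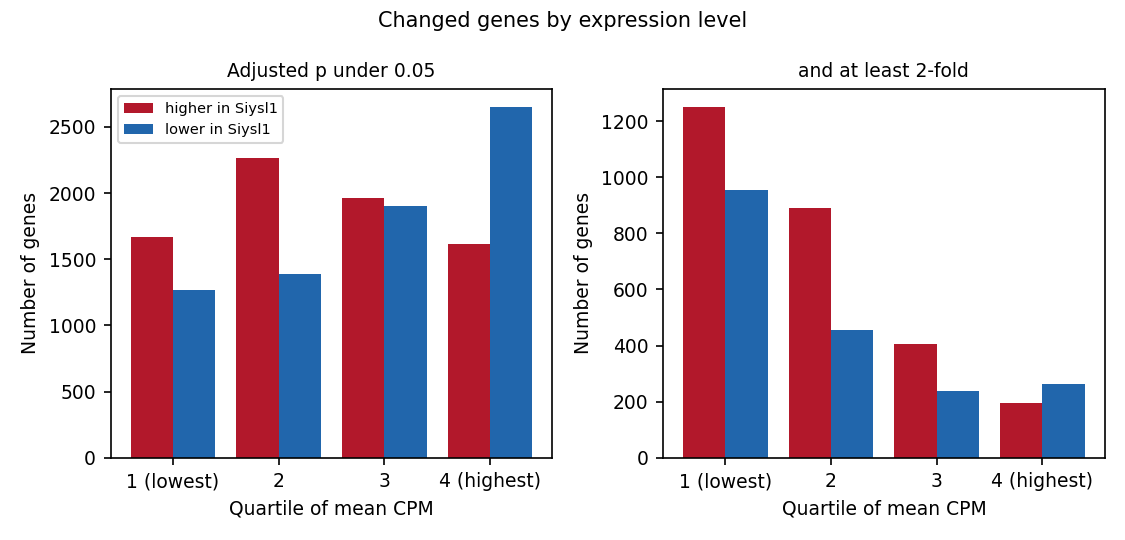
Bars give the number of called genes, higher (red) or lower (blue) in Siysl1, per quartile of mean CPM, for all calls (left) and for calls of at least 2-fold (right). In the highest quartile lower genes outnumber higher ones in both panels, 2653 to 1616 among all calls and 263 to 195 among 2-fold calls.

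Changed genes were found at similar rates on all chromosomes, with more 2-fold changes on chromosome 8. The share of tested genes that were called ran from 57.9% on chromosome 2 to 60.9% on chromosome 8, and no chromosome differed from the other 8 (Fisher's exact test, lowest adjusted p = 0.636; 0 chromosomes at an unadjusted p under 0.05). Among changes of at least 2-fold, chromosome 8 stood out with 334 of 1395 genes, or 23.9%, against 16.4 to 18.8% on the other chromosomes (odds ratio 1.44, adjusted p = 4.78e-07), while chromosome 1 was lowest at 16.4% (odds ratio 0.862, adjusted p = 0.0269). Leaving out each library kept chromosome 8 past the threshold (highest adjusted p = 5.65e-05), whereas chromosome 1 passed in 4 of the 6 cases and had an adjusted p of 0.0887 without WT replicate 1 and 0.0659 without Siysl1 replicate 2. At least 4-fold changes made up 8.10% of the genes on chromosome 8 and 5.10 to 6.81% elsewhere (odds ratio 1.46, adjusted p = 0.00356), with adjusted p between 0.00113 and 0.0358 when each library was left out. Within expression quartiles, an alternative added after seeing the data, the 4-fold excess on chromosome 8 did not pass once adjusted over the 9 chromosomes (odds ratio 1.26, 95% interval 1.02 to 1.55, exact Mantel-Haenszel test, unadjusted p = 0.0304, adjusted p = 0.186). The 2-fold excess did (odds ratio 1.31, 1.14 to 1.5, exact test, adjusted p = 0.00115), chromosome 1 at 2-fold did not (adjusted p = 0.0606), and for any change no chromosome did (lowest adjusted p = 0.348; 1 chromosome, number 8, at an unadjusted p under 0.05). The 4-fold changes on chromosome 8 were 69 higher and 44 lower, against 633 and 637 on the other 8. Of 475 windows of 50 tested genes, 2 were rich in 4-fold changes, 1 on chromosome 8 and 1 on chromosome 9. Each held 11 such genes (one-sided Fisher's exact test against the tested genes outside the window, adjusted p = 0.0277). That test takes genes as independent, as do those of chromosomes, while fold changes of neighbouring genes were correlated. The adjusted p of windows may therefore be too small. Leaving out a library changed which genes were tested and so moved the window borders, and these same windows were not retested. With the moved borders no window passed when any 1 of 5 libraries was left out, and 1 window passed without Siysl1 replicate 3.

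**Figure D4:**
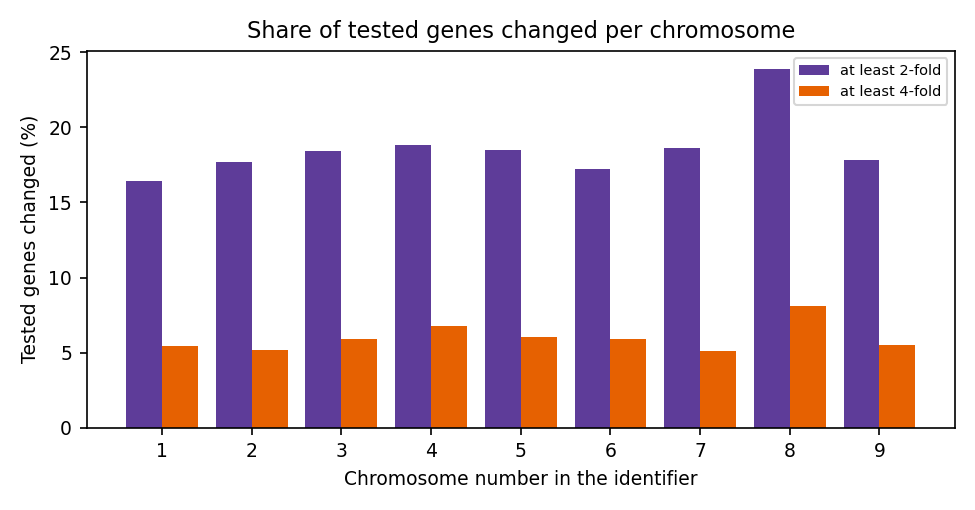
Bars give the percentage of tested genes on each chromosome that changed by at least 2-fold (purple) and at least 4-fold (orange) with an adjusted p under 0.05. Chromosome 8 is highest in both, at 23.9% and 8.10%.

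New loci differed from the genes on numbered chromosomes, but not clearly from annotated genes on unplaced sequence. Of 1279 new loci tested, 602 were called (47.1%), fewer than the 59.3% of genes on the numbered chromosomes (Fisher's exact test, odds ratio 0.61, p = 9.61e-18). Changes of at least 4-fold were in contrast more frequent, at 8.52% against 5.84% (Fisher's exact test, odds ratio 1.5, p = 0.000166). Both shares also follow expression level. The lowest quartile of mean CPM had 46.8% called and 14.9% changed at least 4-fold, the highest 68.0% and 1.32%. New loci were not compared within quartiles, so their expression level may account for these differences. The 143 annotated genes tested on unplaced sequence stood near the new loci, with 48.3% called and 7.69% changed at least 4-fold; they too were called less often than genes on the numbered chromosomes (Fisher's exact test, odds ratio 0.639, p = 0.00806), and with so few genes a difference from the new loci was not found (Fisher's exact test, p = 0.792 for calls and 0.874 for 4-fold changes), which does not show that they are alike. At least 2-fold changes in new loci went up in 135 and down in 154 cases, while on the numbered chromosomes 2589 went up and 1743 down. New loci took 1.35% ± 0.02 of the counts in WT and 1.29% ± 0.02 in Siysl1 (SD, n = 3; exact permutation p = 0.1, the smallest possible).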

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

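Alternatives chosen after seeing the data were no scaling factor, the 100 most abundant genes left out, the test against a 1.5-fold change, the test of chromosomes within expression quartiles and every one for genes of 1 genotype. Leaving out those 100 genes moved log2 fold changes by 0.0083 at the largest, so it says nothing about stability. The 11 other alternatives in model, scaling, filter, tool and input left the counts of called genes within 1.5 times the reported 7515 higher and 7212 lower. Leaving out 1 library gave 6883 to 7664 higher and 6625 to 7463 lower genes, and 2682 to 2882 and 1922 to 2072 at 2-fold. Of the 14727 called genes, 14585 were also called with a replicate block (15222 called), 13091 with DESeq2 (13653) and 11625 with log2 FPKM plus 1 (13223), none of them in the opposite direction. With Siysl1 replicate 1 alone 1 of 11289 shared genes changed direction; that fit assumes that the lone library varies as the WT libraries do. Same-numbered libraries did not pass the limit for pairing, although all 6 correlated best with their own number across genotypes, a hint from the data only. Stricter rules lowered the counts by their construction: 2741 higher and 1911 lower at 2-fold, 2575 and 1783 at 2-fold with an adjusted p under 0.01, and 3140 and 2270 in a test against a 1.5-fold change. On log2 FPKM plus 1 the 2-fold genes were 1643 higher and 842 lower with a mean of at least 1 FPKM and 1692 and 920 without that filter; with a pseudocount of 0.1 1093 were lower. Chromosomes that differed in their share of called genes were 0 for any change and 2 at 2-fold. At 4-fold they were 1, and 1 to 2 without 1 library. Within expression quartiles they were 0 for any change, 1 at 2-fold and 0 at 4-fold. Windows rich in 4-fold changes were 2, and 0 to 1 without 1 library, where the window borders had moved. The cause was not tested. Genes with counts in WT only were 121, or 202 and 44 at minimums of 5 and 30 counts and 137 to 156 without 1 library. In Siysl1 only they were 37, or 74, 14 and 41 to 60. Leaving out a library or lowering the minimum can only keep or add such genes, and raising it can only remove them. The direction of these moves was thus fixed by the definition. The 4 named genes kept direction and call in every alternative that tested them. Depth limits weak genes: below about 3 counts a library cannot tell silence from low expression.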

Other observations

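Tests chosen only after their result was seen were those of splits of the libraries, of batch, of abundant genes, of low depth, of library totals and of neighbouring WT-only genes. Neighbouring genes tended to change together. The correlation of log2 fold changes between next neighbours in identifier order was 0.127 (Pearson, 23686 pairs of tested genes on the 9 chromosomes; Spearman's rho 0.115), above the highest of 1000 shuffles within chromosomes, 0.0249 (p = 0.001, the smallest they can give). It was 0.128 without the genes of 1 genotype. The correlation is across genes of these libraries, and genes are not independent replicates. Beyond the silent genes, 206 genes with counts in both genotypes changed by at least 16-fold by fitted fold, without a floor, 135 lower and 71 higher in Siysl1.

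The breadth of the change, 14727 of 25117 tested genes, was weighed first. A few abundant genes taking the counts are argued against as its source: the 100 most abundant held 15.6% ± 0.19 of the counts in WT and 13.6% ± 0.25 in Siysl1 (SD, n = 3), which shifts all other genes together by 0.033 on the log2 scale (SD 0.005), while without a scaling factor 14744 other genes were called and 14382 passed an edgeR test against a change of 0.044, that shift plus 2 SD. Such a shift would raise all other genes in Siysl1, and 5363 of the 14382 were lower. Small folds made significant by a small replicate spread are part of it but not all, because 5410 genes, 36.7% of the number called, passed a test against a 1.5-fold change. None of the other 9 splits of the 6 libraries into 3 and 3 called a gene (real value 14727, highest other 0). Each of those splits puts both genotypes on each side, so the genotype difference widens the spread within a side and hinders calls. Also, 10 splits are too few for a share under 0.05, so the splits do not decide the question. A batch, growth or harvest difference that follows genotype cannot be told apart from the mutation, since 0 label fields give a batch, and a difference in genetic background or in grain age between the lines also stays open, as untested.

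The 121 WT-only genes against 37 Siysl1-only genes may reflect sequence that the Siysl1 line lacks or carries in a diverged form, as a hypothesis. Low depth is argued against by 44 WT-only genes with at least 30 counts in every WT library, and shallower mutant libraries by a ratio of mean totals, Siysl1 over WT, of 1.02. WT-only genes formed 8 neighbouring pairs, against at most 3 in 1000 random sets matched on expression (permutation p = 0.001, the smallest they can give), but pairs were more frequent than in most random sets elsewhere too: genes with counts in both genotypes and at least 16-fold lower formed 3 pairs (permutation p = 0.02), those at least 16-fold higher 2 (permutation p = 0.01) and Siysl1-only genes 1 (permutation p = 0.037). The sets with counts in both genotypes needed only 1 count in total in each genotype, so some members may be silent in a genotype. They cannot show whether genes that are still present neighbour each other as often. The pairs therefore do not separate absent or diverged sequence from shared control of adjacent genes, and this stays open. Strong repression of genes that stay present stays open as well. Of the genes changed at least 16-fold with counts in both genotypes, 65.5% were lower (95% interval 58.6 to 72.0%), and this interval overlaps that of the WT-only share, 69.2 to 82.9%. An overlap of intervals does not test a difference, and an equal share would not identify repression. The real split gave 121 genes silent in all 3 libraries of one side and the highest other of the 10 splits 2. Only 1 split was as large, the real one, and 10 splits are too few for a share under 0.05. The other splits put both genotypes on each side, where a gene of 1 genotype cannot be silent on a whole side. Their low counts thus follow from the definition and decide nothing.

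The excess of higher genes among 2-fold changes, 58.9%, was weighed last. It depended on the libraries and the method: it was 52.2% with Siysl1 replicate 1 alone against WT (2368 higher, 2171 lower), 55.4% without a filter on low counts, 56.2% with DESeq2 (2768 and 2156) and 67.9% on log2(FPKM + 0.1), and 56.4 to 59.8% when 1 library was left out. The choice of scaling as its whole cause is argued against, since the lowest share over TMM, DESeq2 size factors, upper-quartile and no scaling was 58.3%. Gene length is argued against by a lowest share of 58.15% over 3 equal classes of the length implied by counts and FPKM. Weakly expressed genes alone are argued against because 2 of the 3 upper quartiles of expression also exceeded 55%, at 66.1 and 62.9%, although the highest quartile stood at 42.6%. The mutation itself and a batch following genotype stay open.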
